A study of Mus musculus with 6 samples.

How the data were processed

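Tibialis anterior muscle of 3 wild type and 3 Neb SH3-deleted male mice was profiled. Per the labels' protocols, RNA was extracted with Trizol, checked on a Bioanalyzer and labelled with biotin using the Ambion MessageAmp kit for Illumina arrays. The authors deposited a non-normalized table with, per the file headers, an average signal intensity and a detection p-value for each of 45281 probes on each array. The authors also deposited a table of processed values, which behave as log2 values: its columns share 1 distribution (median 6.10), their ranks follow each array's signal intensity (Spearman 1), and sorted values rise with the log2 of the quantile-averaged signal with a slope of 1.002. The submitters' processing notes name lumi with no version, and whether its values are a plain log2 or a variance-stabilized scale stays unknown, as do further settings, which are not given in the sources used here. No column of sample values was left unused.

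From the signal intensities, the background was corrected with limma's normexp fit from detection p-values (offset 16), and values were taken to log2 and quantile normalized. Detection p-values move in steps that correspond to 936 negative control probes. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept (3422), and for each gene symbol the probe of highest mean over the 6 arrays was used, which left 3011 genes, 352 of them with several kept probes. Such a choice favours bright probes, and further probes of a named gene are given beside its value where they differ from it in sign or by over 1.5 times. For genes of largest weight on the first component, the correlation of a second probe with the first is given instead. Symbols came from the platform annotation: 34885 probes had 1 symbol, 18 several and 10378 none, and 34807 matched a RefSeq gene of the GRCm38.p6 annotation by Entrez number, which changed 0 symbols. A probe without a symbol was tested under its own identifier.

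Signal over background limits these arrays. The median signal per array was 83.3 to 88.9 and the spread of the background 3.18 to 3.62 (SD), and 71.55% of probes were above background on no array, so most genes were not measured and the number of arrays limits the precision of the rest.

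Groups and replicate numbers came from the labels. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, two-sided, no covariate), with Benjamini-Hochberg adjustment over the genes tested. Gene lists were tested with camera (correlation 0.01), adjusted over the 18 of 25 lists with at least 5 tested members. The lists, the tests of genes and lists, the use of other splits of the arrays and all alternatives but one were fixed before the data were examined, and the other tests of explanations in the closing section were chosen later. List symbols were matched with older names through the RefSeq table. The rule for named genes took Neb, the genes past the threshold and, since fewer than 10 passed, the 5 higher and 5 lower genes of smallest unadjusted p, and up to 4 members of smallest p per list, applied here as 4 for a list past the threshold and up to 2 for the others, a limit set after the list results were seen. Genes outside it were named after their values were seen (Cpt1b, Acadvl, and the genes of largest weight on the first component).

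The path from background correction to the gene test, without the choice of 1 probe per gene, was tested on simulated arrays with the measured background. In these, 200 probes per run were changed by 1.5-, 2- or 4-fold. In 5 runs, with a median of 4421 probes tested, 18 unchanged probes were called, and the median residual SD was 0.178 against 0.212 in the real arrays.

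The alternatives were no background correction, an offset of 50, cyclic loess, median scaling, the deposited values, no filter, a detection p under 0.01 on all 6 arrays, the mean of a gene's probes, a replicate block, array weights, eBayes with trend and robust, each array left out, all probes on their own, an adjusted p of 0.1, a 1.5-fold minimum, and for lists an estimated correlation, fry and ranks. Arrays left out were removed from the normalized values of the genes tested. Leaving out both arrays apart on the first component was added after seeing the data. The slide as a block was not run, because the sources used here give no slide.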

Results

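Gene expression was measured on Illumina bead arrays in the tibialis anterior, a fast hindlimb muscle, of male mice at 8 weeks of age on a mixed Sv129/Black Swiss background. The 3 wild type and 3 Neb SH3-deleted samples are biological replicates per the labels, and each was hybridised to 1 array. Nebulin, the product of Neb, is a giant protein that runs along the thin filament of the sarcomere, and its SH3 domain lies at the end anchored in the Z-disc. The comparison asks whether removing that domain alters transcript levels in this muscle. The arrays were dim: of 45281 probes, 5844, 4843 and 4506 were above background (detection p under 0.05) in wild type replicates 1, 2 and 3, and 4000, 4667 and 4041 in Neb SH3-deleted replicates 1, 2 and 3, where 2264 per array would be so by chance. After filtering, 3011 genes were tested, 2553 of them with a symbol. Arrays of the same group correlated at 0.928 to 0.958 (median 0.935) across genes and arrays of different groups at 0.921 to 0.959 (median 0.940), so the genotypes did not separate.

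Neb itself had 1 probe (ILMN_1235161), and it was above background on 0 of 6 arrays, with detection p-values from 0.543 to 0.882. The level of the modified transcript was therefore not measured, no fold is given, and the probe does not check the genotype labels.

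No gene passed an adjusted p of 0.05 (0 of 3011, limma with Benjamini-Hochberg adjustment, smallest adjusted p 0.979). At an unadjusted p under 0.05 there were 129 genes, 49 higher and 80 lower in Neb SH3-deleted muscle, against 151 by chance. The genes of smallest unadjusted p that were higher were Uaca, 1.66-fold (log2 0.73, 95% interval 0.37 to 1.09), Eef1a1, which encodes a translation elongation factor, 1.59-fold (0.67, 0.29 to 1.04), Col6a1, a collagen VI chain, 1.52-fold (0.60, 0.23 to 0.97), Dmpk, the kinase gene of myotonic dystrophy, 1.43-fold (0.51, 0.16 to 0.86), and Oaz1-ps, a pseudogene of antizyme, 1.53-fold (0.62, 0.19 to 1.04). Those that were lower were Lpl (lipoprotein lipase), by a log2 difference of -0.68 (-1.01 to -0.34), Gspt1 (a translation termination factor), -0.66 (-1.05 to -0.28), Slc6a6 (the taurine transporter), -0.57 (-0.90 to -0.24), Scp2 (sterol carrier protein), -0.62 (-0.99 to -0.26), and Phpt1 (a phosphohistidine phosphatase), -0.55 (-0.88 to -0.21). Eef1a1 and Oaz1-ps have near-identical copies elsewhere in the genome, so their probes may read more than 1 gene. A second probe of Scp2 gave -0.09, that of Eef1a1 0.34 and that of Col6a1 0.28. Without background correction the sizes of dim genes were smaller, with Slc6a6 at -0.17 and Phpt1 at -0.16.

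The normalized levels per array show how these differences compare with the spread between animals. Lpl was at 8.31 ± 0.15 (log2 intensity, SD, n = 3) in wild type and 7.63 ± 0.04 (SD, n = 3) in Neb SH3-deleted muscle, and Uaca at 6.72 ± 0.10 and 7.45 ± 0.20 (SD, n = 3 each). The groups did not overlap for 281 genes (9.33%), where 10% is the share that chance gives with 3 against 3. The median 95% half-width was 0.40 on the log2 scale, and for 2925 genes (97.14%) the interval lay within 1 log2 unit of 0. On simulated arrays with the same background, 4.48% of 1.5-fold, 25.7% of 2-fold and 63.0% of 4-fold changes were recovered. These are shares of all changed probes, of which 289 of 335, 300 of 335 and 272 of 330 passed the detection filter. Because the simulated residual SD was lower (0.178 against 0.212) and 200 probes changed per run, they do not give the power of the real test. A true log2 change of 1 was fitted at a median of 0.44, so the path understated simulated changes.

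**Figure D1:**
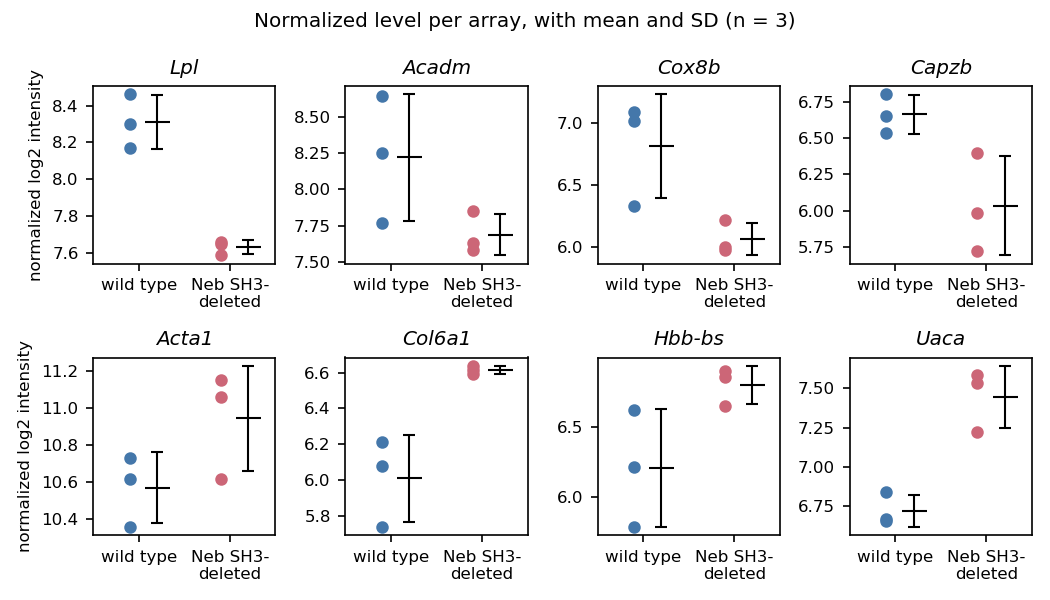
Normalized log2 intensity (vertical axis) of 8 named genes in wild type and Neb SH3-deleted muscle, with 1 point per array and the mean and SD beside them (n = 3 per group); the axes differ between panels and do not start at 0. Lpl, Acadm, Cox8b and Capzb had lower means in Neb SH3-deleted muscle and Acta1, Col6a1, Hbb-bs and Uaca higher ones, Acta1 turning to -0.01 with median scaling, and none passed the adjusted threshold.

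Genes of fatty acid uptake and oxidation were lower in Neb SH3-deleted muscle as a list, the one call among 18 lists tested. Of its 14 tested members 12 were lower and 2 higher, with a median log2 difference of -0.20. In limma's camera test against all other genes the adjusted p was 0.0156. Of the 14 members 9 were above background on all 6 arrays. The others, all lower, were above background on all wild type arrays but not on all Neb SH3-deleted arrays. With a detection p under 0.01 required on all 6 arrays, the adjusted camera p was 0.0375. With an estimated correlation between members (0.318) the call was lost, at an unadjusted camera p of 0.192. The adjusted p was then 0.598, a value that several lists share through the adjustment. Its members of smallest unadjusted p were Lpl, which releases fatty acids from circulating triglycerides (-0.68), Acadm, the medium-chain acyl-CoA dehydrogenase (-0.54, interval -1.02 to -0.05), Acaa2, the thiolase of mitochondrial β-oxidation (-0.51, -0.99 to -0.03), and Etfb, an electron transfer flavoprotein subunit (-0.45, -1.07 to 0.18). Etfb had a second probe at 0.18, and Acaa2 further probes at -0.11 and -0.46. Acadm was at -0.32 without wild type replicate 2, Acaa2 at -0.31 without Neb SH3-deleted replicate 1, and Etfb at -0.10 without Neb SH3-deleted replicate 2 and -0.74 without Neb SH3-deleted replicate 1. Across all genes 0 members passed, and adjusted over the list alone 1 did (Lpl, adjusted p 0.0158 by limma). Cpt1b and Acadvl were above background on 3 wild type arrays and 0 Neb SH3-deleted arrays, as were 68 of the 3011 genes, beside the lower number of detected probes in 2 of those 3 arrays, and their differences were -0.22 (-0.55 to 0.10) and -0.14 (-0.46 to 0.19). The call ended without wild type replicate 2 (adjusted p 0.471), without Neb SH3-deleted replicate 2 (0.106) and without Neb SH3-deleted replicate 3 (0.127), with array weights (0.0504), with camera on ranks (0.0724) and with fry (0.576), over a range of 0.000667 to 0.598. Without Lpl the adjusted p was 0.0816, while 11 of the other 13 members were lower, with a median of -0.19 and a mean of -0.20 (-0.23 with Lpl).

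Other metabolic genes did not pass. In oxidative phosphorylation 24 of 38 members were lower (median -0.10, camera adjusted p 0.332), among them Cox8b, a cytochrome c oxidase subunit (-0.75, 95% interval -1.23 to -0.28), and Atp5j, a subunit of ATP synthase (-0.53, -0.87 to -0.20, with a second probe at -0.34). With median scaling in place of quantile normalization this list was past the threshold, at an adjusted p of 0.00377. An estimated correlation was not combined with median scaling. With quantile normalization the estimate was 0.00817, and the unadjusted camera p was then 0.190 (adjusted p 0.598). In glycolysis and glycogen 8 of 15 members were higher and 7 lower (adjusted p 0.948), with Gapdh at -0.46 (-0.88 to -0.05) and Gys1, glycogen synthase, at -0.32 (-0.75 to 0.11). Without Neb SH3-deleted replicate 1 Gapdh was at -0.31 and Gys1 at -0.18.

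Lists of the contractile apparatus, where nebulin sits, did not pass the threshold. Of 16 thin filament genes and nebulin partners 7 were higher and 9 lower (median -0.04, camera adjusted p 0.928). Capzb, the β subunit of the protein that caps actin filaments at the Z-disc, was at -0.63 (95% interval -1.06 to -0.20), while its further probes were at -0.07 and -0.26, and Acta1, skeletal α-actin, was at 0.38 (-0.04 to 0.80), turning to -0.01 with median scaling. Of 19 Z-disc genes 9 were higher and 10 lower (adjusted p 0.439), with Tcap (telethonin) at 0.45 (-0.06 to 0.95, with a second probe at 0.25) and Actn2 (α-actinin 2) at -0.34 (-0.79 to 0.10). The slow fibre programme had 3 of 6 members higher (adjusted p 0.948), with Atp2a2 at -0.23 and Myl2 at -0.26, and the fast fibre programme 9 of 15 (adjusted p 0.620), with Myoz1 at -0.42 and Mybpc2 at -0.29. Calcium handling and excitation-contraction coupling had 13 of 17 members higher (median 0.07, adjusted p 0.219), with Orai1 at 0.42 and Jph2 at 0.26. This list passed with cyclic loess (adjusted p 0.0436), with which an estimated correlation was not combined. With quantile normalization and an estimated correlation (0.0907) its unadjusted camera p was 0.266 (adjusted p 0.598). In the membrane, costamere and dystrophin list 4 of 9 were higher (adjusted p 0.928), with Utrn (utrophin) at 0.49 (0.07 to 0.90, adjusted p 0.979 by limma). Utrn was dim, at mean log2 levels of 4.27 and 4.75. It was above background on 0 wild type and 3 Neb SH3-deleted arrays, as were 20 of the 3011 genes tested. With 1 array left out, Tcap was at 0.24 without wild type replicate 3, Actn2 at -0.22 without wild type replicate 2 and -0.55 without wild type replicate 3, and Mybpc2 at -0.44 without wild type replicate 3. Likewise Atp2a2 was at -0.0735 without Neb SH3-deleted replicate 1 and -0.40 without wild type replicate 2, and Myl2 at 0.11 without wild type replicate 1 and -0.69 without wild type replicate 2. Myoz1 was at -0.0155 without Neb SH3-deleted replicate 1 and -0.66 without Neb SH3-deleted replicate 3, and Orai1 at 0.26 without Neb SH3-deleted replicate 2 and 0.69 without Neb SH3-deleted replicate 1. Outside the fatty acid and fibroblast lists, 0 members of any list passed when adjusted over the list alone.

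Stress and turnover genes did not pass with camera either. In the stretch and titin-linked list 6 of 7 members were higher (median 0.14, adjusted p 0.219), with Ankrd23, a titin-binding ankyrin repeat protein, at 0.56 (95% interval 0.03 to 1.09, and 0.27 without Neb SH3-deleted replicate 3). In the list of ubiquitin ligases, autophagy and atrophy 5 of 9 were higher (median 0.09, adjusted p 0.205), with Mt1, a metallothionein, at 0.67 (0.14 to 1.21) and Ulk1, a kinase that starts autophagy, at 0.46 (0.07 to 0.84, with a second probe at 0.165). This was the 1 list called by fry (adjusted p 0.0402), which asks whether a list's genes move one way on balance and compares them with no other genes. Heat shock and chaperone genes had 5 of 6 members higher (adjusted p 0.416) and immediate early genes 5 of 5 (adjusted p 0.332). Genes of regeneration and embryonic muscle had 5 of 7 members lower (median -0.24, adjusted p 0.332), with Igf2 at -0.36 and Cdkn1c at 0.45 (0.19 without Neb SH3-deleted replicate 1). Neighbours of Neb on chromosome 2 had 3 of 5 members higher (adjusted p 0.948), with Pkp4 at -0.37 and Mmadhc at 0.09. Pkp4 was at -0.0032 without Neb SH3-deleted replicate 3 and -0.60 without Neb SH3-deleted replicate 1, and Mmadhc at -0.0628 without wild type replicate 3 and 0.18 without wild type replicate 1. The circadian clock had 2 tested members and the interferon response 3, too few to test, with Tef at -0.25 and B2m at -0.24, while a second probe of B2m was at 0.07. Tef was at -0.13 without wild type replicate 1 and -0.41 without wild type replicate 2, and B2m at -0.0757 without Neb SH3-deleted replicate 1 and -0.39 without Neb SH3-deleted replicate 3.

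**Figure D2:**
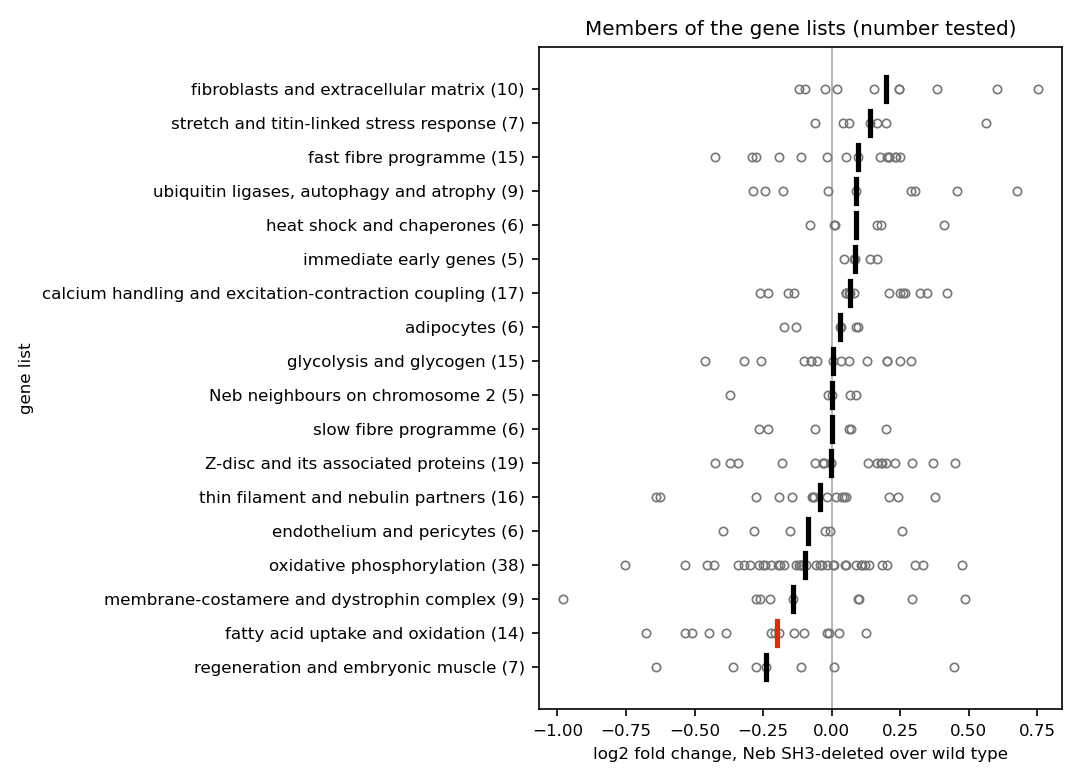
Log2 fold change of Neb SH3-deleted over wild type (horizontal axis) for each tested member (open circles) of the 18 gene lists (vertical axis, number of members in brackets), with the list's median as a bar, red where camera passed an adjusted p of 0.05. The fatty acid list, at a median of -0.20, is the list in red, a call lost with an estimated correlation (adjusted p 0.598).

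Markers of other cell types gave values close to the threshold for connective tissue. Of 10 fibroblast and extracellular matrix genes 7 were higher in Neb SH3-deleted muscle (median 0.20, camera adjusted p 0.0518, and adjusted p 0.598 with an estimated correlation), with Col6a1 at 0.60 and Sparc, a collagen-binding matrix protein, at 0.75 (95% interval -0.17 to 1.68). Sparc was at 0.21 without wild type replicate 2 and at up to 1.05 with another array left out, and its second probe was at 0.49. Adjusted over the list alone 1 member, Col6a1, passed (adjusted p 0.0442 by limma), and its second probe was at 0.28. The adjusted p of the list ran from 0.00318 to 0.598 over the alternatives, with 5 of 20 under 0.05. Endothelial and pericyte markers had 5 of 6 members lower (adjusted p 0.462), with Rgs5 at -0.40 (-0.25 without wild type replicate 3), and adipocyte markers 4 of 6 higher (adjusted p 0.928). The 3 erythrocyte genes measured were all higher (median 0.59), with Hbb-bs at 0.59 (0.12 to 1.06) and Hbb-bt at 0.61 (-0.04 to 1.27), β-globin genes whose near-identical sequences the probes may not separate. Further probes of Hbb-bs were at 0.08, 0.18, 0.70 and 1.085 and a further probe of Hbb-bt at 0.39. Both genes were lowest in wild type replicate 1, and without that array Hbb-bs was at 0.38 and Hbb-bt at 0.24. Macrophages and leukocytes had 4 tested members, with Lyz2 at -0.26, and nerve, Schwann cells and junction (Rapsn, 0.14) and satellite cells and myoblasts (Itga7, -0.28) had 1 each. Lyz2 was at -0.0298 without Neb SH3-deleted replicate 3 and -0.67 without Neb SH3-deleted replicate 2, and Rapsn at 0.0112 without Neb SH3-deleted replicate 3 and 0.24 without Neb SH3-deleted replicate 1. Of the sex-linked check genes 0 passed the filter. Median, mean and test differed in sign for the Z-disc, slow fibre, glycolysis, Neb neighbour and adipocyte lists.

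The largest component of variation did not follow genotype. The first principal component (31.75% of the variance) set wild type replicate 2 (9.98) and Neb SH3-deleted replicate 1 (11.3) apart from the other arrays, which lay between -5.94 and -4.80, and on the second (23.46%) Neb SH3-deleted replicate 3 was at -12.2. Without wild type replicate 2 and Neb SH3-deleted replicate 1, a choice made after seeing the data, 0 genes and 0 lists passed, with the fatty acid list lower at an adjusted p of 0.197.

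**Figure D3:**
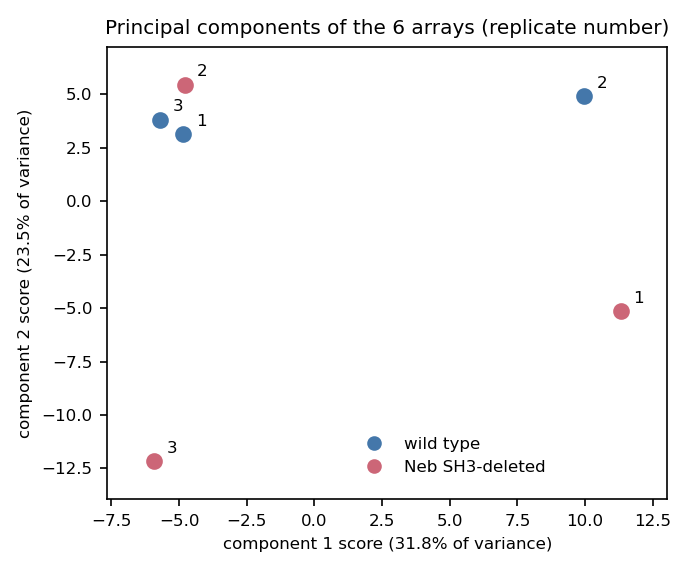
Scores of the 6 arrays on the first (horizontal axis, 31.75% of the variance) and second (vertical axis, 23.46%) principal component of the normalized log2 values, with replicate numbers beside the points. Wild type replicate 2 and Neb SH3-deleted replicate 1 lie at 9.98 and 11.3 on the first component, and the other 4 arrays lie below 0.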

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

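Leaving out both arrays apart on the first component was chosen after seeing the data; the other alternatives were planned, and the slide as a block was not run, because the sources used here give no slide. The number of genes past an adjusted p of 0.05 stayed at 0 in 21 of 21 alternatives (limma), with 32 to 1249 genes at an unadjusted p under 0.05 (129 in the reported analysis), the extremes coming from the strictest detection filter (1030 genes tested) and from no filter (29453 genes tested). The number of lists past the threshold moved from 1 to 3 with cyclic loess, to 2 with median scaling, the mean of a gene's probes and the replicate block, and to 0 with array weights, an estimated correlation, camera on ranks and both arrays left out, and ran from 0 to 2 with each array left out. Whether the replicate numbers pair the animals is not known. Deviations of same-numbered samples from their group means correlated at -0.21, -0.15 and 0.09. Not every sample correlated best with its own number, the highest value (0.301) joining wild type replicate 2 and Neb SH3-deleted replicate 1. Deviations within a group depend on each other, so these values show no pairing but cannot exclude one. With the replicate block 0 genes passed, and the fibroblast list joined the fatty acid list. The fatty acid list kept its direction in 21 of 21 alternatives and its call in 13, losing it with array weights (0.0504), ranks (0.0724), both arrays left out (0.197), fry (0.576) and an estimated correlation (0.598), and ranging from 0.000667 to 0.471 with each array left out. Other lists passed under an alternative in 8 of 348 values, and their direction turned in 35, at these adjusted p-values. With median scaling these were fast fibre (0.818), Z-disc (0.921) and glycolysis (0.220). With no filter they were glycolysis and slow fibre (0.986 each) and heat shock and membrane-costamere (0.889 each). With the mean of probes they were glycolysis and slow fibre (0.975 each). With cyclic loess they were glycolysis and Neb neighbours (0.917 each), and with fry the same lists (0.928 each). With array weights they were glycolysis (0.823) and Neb neighbours (0.968), with trend and robust glycolysis (0.980), and with the replicate block Neb neighbours (0.972). With both arrays left out they were fast fibre (0.949), glycolysis (0.539) and Neb neighbours (0.982). With each array left out, the lists that turned at least once ran from 0.509 to 0.859 (adipocytes), 0.468 to 0.859 (glycolysis), 0.771 to 0.950 (membrane-costamere), 0.671 to 0.898 (Neb neighbours), 0.471 to 0.896 (slow fibre), 0.598 to 0.844 (thin filament) and 0.136 to 0.821 (Z-disc). Of 55 named genes 46 kept their sign throughout, and none passed (lowest adjusted p 0.288), but sizes moved. With an array left out 35 moved by over 1.5 times (Myoz1 from -0.42 to -0.0155, Pkp4 from -0.37 to -0.0032, Sparc from 0.75 to 0.21). With another setting, leaving out both arrays apart included, 54 did (Phpt1 from -0.55 to -0.15 and Slc6a6 from -0.57 to -0.16 with the deposited values). Signs turned with median scaling for Acta1 (-0.0058) and Mmadhc (-0.0062), with both arrays left out for Ccn2 (-0.27), Dbp (0.13) and Dgat2 (0.0739), and with single arrays left out for Ccn2 (-0.16 to 0.40), Cryab (-0.13 to 0.40), Dbp (-0.28 to 0.24), Dgat2 (-0.41 to 0.24), H2-Ab1 (-0.11 to 0.21), Igf1 (-0.0459 to 0.26), Mmadhc (-0.0628 to 0.18) and Myl2 (-0.69 to 0.11). Without background correction, or with a larger offset, a constant stays under the signal, which by arithmetic shrinks the log2 differences of dim genes. Apart from this and from the smaller number of arrays or genes, the cause was not tested.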

Other observations

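Apart from the estimated correlation and the other splits of the arrays, the tests of explanations below were chosen after the patterns they concern were seen, and that of slow fibres also after values it measures were seen. Of the 100 genes and probes of largest weight on the first component, 49 were lower in both wild type replicate 2 and Neb SH3-deleted replicate 1 than in each of the other 4 arrays, 35 were higher in both, and 16 overlapped. They were picked by their weight on the component that sets these arrays apart. A high share without overlap is therefore built in, and the counts show only the directions. The genes given here were named after their values were seen. Mef2c, a transcription factor of muscle, was at 6.59 and 6.21 (normalized log2 intensity) in these and at 8.93, 9.24, 9.39 and 8.65 in the others. Hspa8, a constitutive chaperone, was at 5.22 and 4.99 against 6.98 to 7.23, and Eef2, a translation elongation factor, at 4.88 and 4.29 against 5.81 to 7.09. Ccng1, a cyclin gene that responds to p53, was at 4.85 and 5.11 against 6.06 to 7.30. In the other direction, Slc46a3 was at 5.97 and 5.91 against 4.56 to 4.96, and Mb, which encodes myoglobin, at 8.93 and 8.73 against 7.83 to 8.34. Each value is that of a single probe. Second probes correlated with it over the 6 arrays at 0.478 (Mef2c), 0.391 (Hspa8), 0.306 (Ccng1), 0.796 (Eef2) and 0.924 (Mb). Wild type replicate 2 and Neb SH3-deleted replicate 1 detected 4843 and 4000 probes, the second highest and the lowest number of the 6. A low number of detected probes is therefore not common to both. Among tested genes, 68 had a probe above background on all wild type arrays and no Neb SH3-deleted array and 20 the reverse, 88 in all, where the other 9 splits of the arrays gave a median of 65 and at most 109.

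For the first component, a linked stretch of the genome that segregates in the mixed background would place genes of large weight near each other. Among the 100 genes of largest weight, 2 pairs lay at most 5 annotated genes apart, as in the median of 10000 random sets (2, with a 95th percentile of 4). Close neighbours were thus not enriched. Only 2545 tested genes had a position, so this count cannot exclude a longer stretch whose tested genes lie farther apart. A probe-specific signal, such as a variant under a probe, stays open, since second probes of the 30 genes of largest weight that have one correlated with the first at a median of 0.498. A smaller share of slow fibres in these samples stays open too: the mean weight of the 6 slow fibre genes lay at the 1.95th percentile of 10000 lists matched on mean level, but 3 of them (Myl2, Atp2a2 and Csrp3) were lower in both arrays than in each of the others, 2 overlapped and 1 was higher. Myl2 was at 4.20 and 4.22 against 4.94 to 5.80, while Myl3 was at 6.59 and 6.84 against 6.22 to 7.51, Ankrd2 at 4.48 and 4.50 against 4.37 to 4.61, Fhl1 at 9.10 and 9.24 against 8.22 to 9.04, and a second probe of Csrp3 at 4.95 and 4.63 against 4.53 to 5.06, and Mb, abundant in oxidative fibres, was higher in both. The arrays apart are 1 of each genotype, and no biological explanation was tested by the design.

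For the fatty acid list, lower mean levels were not confined to Lpl. Of the other 13 members 11 were lower, with a median of -0.19 against -0.20 with Lpl. Their mean was -0.20 (SD 0.21 over members) against -0.23 (SD 0.24). A median moves little when any 1 member is dropped, so it says little about Lpl. At a correlation of 0.01 the unadjusted camera p of the 13 members was 0.00906, under a bound set before the test but after the pattern was seen. That correlation is far below the 0.318 estimated for the list, so this p cannot decide whether Lpl carries it. Without Lpl the call was lost, the adjusted camera p rising from 0.0156 to 0.0816. Members that vary together in these arrays are a candidate explanation. At the estimated correlation the unadjusted camera p of the list was 0.192, against 0.000869 at a correlation of 0.01. The adjusted p was 0.598 with Lpl and without it. Several lists share that value through the adjustment, so the equality says nothing about Lpl. A contribution of the arrays apart on the first component stays open. In the other 4 arrays 9 of 14 members were lower, with a median of -0.18 and a mean of -0.16 (SD 0.28). The unadjusted camera p was 0.0328 there (adjusted p 0.197). Left out singly, the arrays apart moved the call in opposite directions. The adjusted camera p was 0.471 without wild type replicate 2 and 0.00131 without Neb SH3-deleted replicate 1, against 0.0156 with all 6 arrays. The bound set before the test for the p of 0.0328 was too loose to exclude such a contribution. The list also passed camera in 2 other splits of the 6 arrays, both with wild type replicate 2 and Neb SH3-deleted replicate 1 on one side. Their adjusted p-values were 0.00477 and 0.0144, against 0.0156 in the real split, where these arrays lie on opposite sides. Further splits with both on one side did not pass (0.404 and 0.0591). Of the 10 splits, too few for a share under 0.05, 5 gave at least 1 list, with 1 in the real split and at most 4 in another, and an effect of the deletion on these genes remains untested beyond these values.

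For the absence of called genes, dim probes could hide changes, which would leave an excess of small p-values among bright genes. Of 1341 genes above background on all 6 arrays 77 had an unadjusted limma p under 0.05, 5.74%, against 4.28% of all genes tested. The 95% exact binomial interval, which treats genes as independent, was 4.56 to 7.12%. It includes 5%, so no excess was shown, but it is too wide to exclude one. Whether dim probes hide changes therefore stays open. Because the real split gave 0 genes, all 10 splits reach that count by construction, so it says nothing about chance; the highest of the others gave 2. Genes below background on these arrays were not measured, and nothing follows for them.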
